A study of Mus musculus with 30 samples.

How the data were processed

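RNA from the primary visual cortex (V1) of mice was measured at 3 ages, postnatal days 14, 28 and 60 (P14, P28 and P60). Per the labels' protocols, the mice were reared under standard conditions, V1 was microdissected from litters, RNA was extracted with Trizol, and biotinylated cRNA was made from 6 µg of total RNA. There were 3 litters at P14, 3 at P28 and 4 at P60, and the RNA of each litter was hybridised to 3 types of Affymetrix array, MG-U74Av2, MG-U74Bv2 and MG-U74Cv2, called chips A, B and C here. Every sample title opens with the words litter 1 and then gives an age and a second litter number, which the source field repeats. The second number was taken as the litter, so the 30 arrays were treated as 10 litters, and every p-value assumes that these are separate litters. How many animals made up a litter sample, and of which sex, is not given in the sources used here.

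The deposited values are signal intensities on a linear scale, 1 per probe set and array, calculated with MAS5 per the submitters' processing notes. The version of MAS5 is not given in the sources used here. The 2% trimmed mean of every array in the deposited tables is 500, so the arrays had been scaled to a common level, and no further scaling was applied in the main analysis. The tables hold 12488 probe sets for chip A, 12477 for chip B and 11934 for chip C, among them 66 array control probe sets per chip. They hold no detection calls and no probe-level intensities, so a detection filter and a new summary from single probes were not used here.

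Gene symbols came from the annotation table supplied with the arrays, brought up to date through the gene ID, which matched for 99.7% of the symbols. On chip A 10855 probe sets had 1 symbol, 396 had several and 1237 had none listed. On chip B these numbers were 10603, 178 and 1696, and on chip C 7739, 150 and 4045. No gene was named from a probe set with several symbols. Where a gene had several probe sets, 1 was kept, from chip A if possible, otherwise from B or C, and within a chip the one with the highest mean log2 signal. This left 11240 genes. Probe sets whose names carry the suffixes f, g, i, r or s were designed under relaxed rules or shared between transcripts. This is pointed out for some of the named genes, such as Cadm1 and Igf2, and not for all.

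Signals were analysed as log2 of the signal plus a constant, the 20th percentile of the chip type's values (38.6 on chip A, 57.8 on B and 44.0 on C). A probe set was tested if it was above the chip type's median (207, 252 and 183) on at least 3 arrays and was not an array control. This left 20724 probe sets, 6819 on chip A, 7005 on B and 6900 on C. Each chip type was fitted separately with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a variance trend). All 10 litters entered each fit with age as the only term, and the Benjamini-Hochberg adjustment ran over the 3 chip types together with a threshold of 0.05. The comparisons were P28 with P14, P60 with P28, and P60 with P14. A moderated F-statistic over both age contrasts tested the 3 ages together, and a probe set counted as highest or lowest at P28 if both neighbouring comparisons passed with opposite signs. Standard errors are those of limma. The number of arrays limits the precision. As a measure of background, 15 probe sets per chip for Bacillus control transcripts gave 95th percentiles of 98.4 on chip A, 153 on chip B and 252 on chip C, and named genes with an age mean below that level are pointed out. Their log2 changes depend on the added constant and are not measured sizes.

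Fixed gene lists were tested with limma's camera on the 1 probe set per gene, with a preset correlation between genes of 0.01, adjusted over 30 lists. The same test was also run with the correlation estimated for each list. The cell type lists were myelin and mature oligodendrocyte, oligodendrocyte progenitor, astrocyte, microglia, endothelial and mural, meningeal and fibroblast, choroid plexus, blood cells, hippocampal formation, and GABAergic interneuron. The other lists were GABA-A receptor subunits, glutamate receptor subunits, activity-regulated and immediate early genes, actin cytoskeleton, axon growth and immature neuron, proliferation, perineuronal net and extracellular matrix, synaptic vesicle and release, postsynaptic density and calcium signalling, voltage-gated channels, neurofilament and mature axon, mitochondrial respiratory chain, glycolysis, cholesterol synthesis, ribosomal proteins, MHC class I and complement, insulin-like growth factor, neurotrophins and receptors, circadian clock, and heat shock and stress. A sex-linked list was looked at but not tested. The actin list was included because the study is known to have looked at actin genes. For each list, members past the threshold were also counted after adjustment over the list alone. A list score is the mean over members of the log2 signal in a litter after the gene's mean over the litters was taken away.

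The design, the lists, the other settings to try and the rule for naming genes were chosen before the data were examined. The rule names, for each comparison, up to 12 genes with the largest rises and 12 with the largest falls among those past the threshold without overlap of the litters of the 2 ages. It also names up to 4 members of each list with the largest change, and members that passed against their list's direction. Symbols of unnamed clones were passed over. Genes named outside the rule are marked as such.

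The other settings were quantile normalisation, scaling to a common median, other constants or a floor, no filter or one at the 70th percentile, no variance trend, a fold change of at least 1.5 on top of the threshold, only the 2 ages compared in the fit, the litter number as a block, array weights, the mean of a gene's probe sets in place of 1, estimated correlations, and each litter left out in turn. The arrays then showed that P14 litter 1 had 3'/5' ratios of control transcripts far above those of all other arrays, and that P60 litters 1 and 4 on chips A and B and P60 litter 2 on chip C had low correlations with the other arrays. A restricted set without those arrays, and a set without those P60 arrays only, were chosen after seeing the data. In the restricted set lists were tested with cameraPR, which takes no estimated correlation. Values with all litters come first, and for the main results those without P14 litter 1 and from the restricted set stand beside them. Limma fits of the restricted set rest on 2 P14 litters.

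The steps were tested on simulated data drawn from the real means and spreads for P60 against P14 over 20724 probe sets. Of planted changes, 18.9% of those of 1 on the log2 scale and 71.8% of those of 2 were recovered, and 4.46% of the calls were false. In 20 draws with no change the median number of calls was 0. Camera called 5 of 5 lists of 25 genes shifted by 0.5 on the log2 scale and 0 flat ones. The simulated probe sets varied independently of each other and no simulated array stood apart. These rates therefore do not cover genes that vary together or arrays of poor quality, both of which the real data may hold. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.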

Results

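Gene expression was measured in the primary visual cortex of mice at P14, around eye opening, at P28, within the critical period for ocular dominance plasticity, and at P60, in the young adult. There were 3 litters at P14, 3 at P28 and 4 at P60, each on 3 array types that together hold 36899 probe sets. The 2% trimmed mean signal was 500 on each of the 30 arrays, and 20724 probe sets were bright enough to be tested, for 11240 genes. The p-values rest on litters, and the number of arrays limits the precision.

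The arrays were not of even quality. On P14 litter 1 the signal ratio of the 3' to the 5' probe sets lay between 9.57 and 12.2 for Gapdh and between 12.2 and 12.8 for Actb over the 3 chips. On the other 27 arrays these ratios ran from 0.741 to 1.32 and from 1.04 to 1.5. P60 litters 1 and 4 had mean correlations with the other arrays of 0.910 and 0.923 on chip A, where the remaining arrays apart from P14 litter 1 lay between 0.936 and 0.952. On chip B the values of those litters were 0.884 and 0.883, and on chip C it was P60 litter 2 that was lowest, at 0.860. Values with all litters are therefore followed, for the main results, by those without P14 litter 1 and by those of a restricted set, chosen after seeing the data, which also leaves out those P60 arrays.

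**Figure D1:**
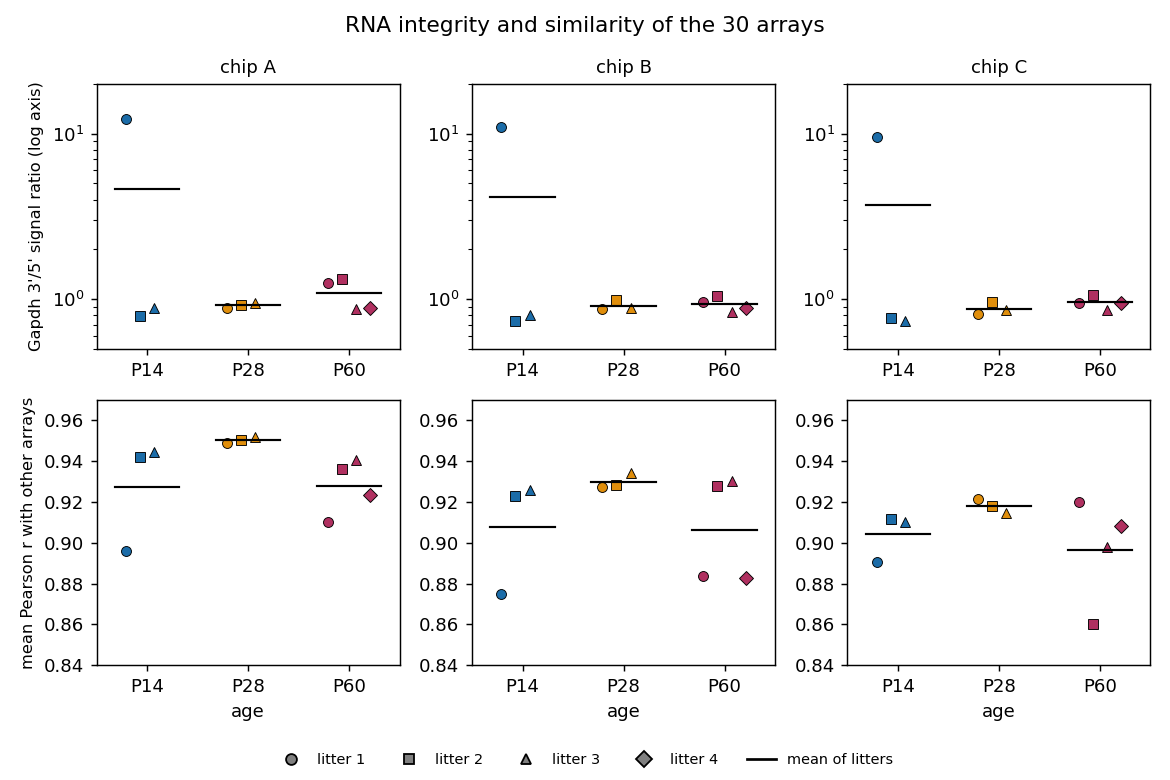
Upper panels show the ratio of the Gapdh 3' to 5' signal on a log axis and lower panels the mean Pearson correlation of each array with the other arrays of its chip type, for chips A, B and C. Each point is the array of 1 litter, by age. P14 litter 1 lies between 9.57 and 12.2 in the ratio and all other arrays lie at or below 1.32.

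The comparison of P28 with P14 asks what changes in V1 between eye opening and the critical period. Genes of growing axons and young neurons shifted down as a group and genes of myelin shifted up in camera with its preset correlation. Neither list passed with an estimated correlation (adjusted p = 0.0607 and 0.147). The clearest single change was a fall of Cadm1, which encodes a synaptic adhesion molecule also called SynCAM1. Myelin genes such as Mag, Mal, Mobp and Mbp, and immediate early genes such as Junb, were higher at P28 in the means, though none of them passed the test over all probe sets with all litters. Actin cytoskeleton genes shifted slightly down with the preset correlation and did not pass with an estimated one (adjusted p = 0.221) or when any 1 of 5 litters was left out.

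With all litters, limma called 1 of 20724 probe sets between P14 and P28, and 1632 had an unadjusted p under 0.05, against 1036 expected by chance. Cadm1 fell from a signal of 5162 ± 1060 (SD, n = 3) at P14 to 1018 ± 83.6 (SD, n = 3) at P28, a log2 change of -2.28 with a standard error of 0.218 and an adjusted p of 0.00465. Over the alternatives its adjusted p ran from 1.55e-06 to 0.229, and it was 0.0755 without P28 litter 1 and 0.062 without P28 litter 3. The probe set is of the f type, which can be shared between related transcripts, and the other 2 Cadm1 probe sets had log2 changes of -0.67 and -0.28. Without P14 litter 1, 26 probe sets passed, 10 higher and 16 lower at P28, and in the restricted set 208 passed, 83 higher and 125 lower. The single call with all litters was among both, which reuse arrays on which it was made. P14 litter 1 had no part in making these larger counts. On an axis from the mean of the other P14 litters at 0 to P28 at 1, its median position was 0.608 over the 26 probe sets and 0.854 over the 208, and it was nearer to P14 in 11 and in 72 of them. Of the 26, it was nearer to P14 in 9 of the 16 falls (median 0.277) and in 2 of the 10 rises (0.95). Of the 208, it was so in 41 of the 125 falls (0.917) and 31 of the 83 rises (0.729), so it bore out most of the 16 falls but not most of the other calls.

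Of the myelin and mature oligodendrocyte list, 23 genes were measured and 20 were higher at P28, with a median log2 change of 0.57 (camera, adjusted p = 1.37e-08, and adjusted p = 0.147 with an estimated correlation). None passed over all probe sets and 8 rose when adjusted over the list alone. The largest changes were those of Mag, an adhesion protein of the myelin sheath, at 1.57 (adjusted p = 0.162), Mal at 1.40 (0.145), Mobp at 1.32 (0.594) and Mbp at 1.15 (0.308). Mean signals went from 260 to 810 for Mag and from 2724 to 6252 for Mbp. There were 2 members past the test without P14 litter 1 and 8 in the restricted set, among them Mobp at 2.16 (adjusted p = 0.0141) and Mal at 1.67 (0.00849). Over all settings the adjusted p of Mobp ran from 0.000815 to 0.993 and that of Mal from 0.000136 to 0.682. In P14 litter 1 itself Mobp stood at 3376, against 441 and 717 in the other P14 litters, whereas Mbp stood at 2681, near their 2519 and 2973.

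Of the axon growth and immature neuron list, 25 genes were measured and 5 were higher at P28, with a median log2 change of -0.48 (camera, adjusted p = 3.01e-08, and adjusted p = 0.0607 with an estimated correlation). None passed over all probe sets and 9 fell when adjusted over the list alone. The largest changes were those of Dpysl5, a regulator of growth cones, at -1.38 (adjusted p = 0.475), Nrep at -1.18 (0.235), Cd24a at -1.04 (0.423) and L1cam at -1.04 (0.633), whose P28 mean lay below the Bacillus controls. With P14 litter 1 left out, 2 members passed and both this list and the myelin list had an adjusted p of 0.0494 with an estimated correlation, with which neither had passed with all litters. The restricted set had 7 falling members, with Dpysl5 at -1.99 (adjusted p = 0.00859, and from 0.00255 to 0.99 over all settings).

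Another 4 lists passed camera between P14 and P28, and none of them did with an estimated correlation. Activity-regulated and immediate early genes, which neurons switch on when they fire, shifted up, with 22 of 28 higher and a median of 0.29 (adjusted p = 0.0403, and adjusted p = 0.608 with an estimated correlation). None of them passed over the list alone. Junb stood at 1.40 (adjusted p = 0.324), Per1 at 0.90 (0.662), Nr4a1 at 0.85 (0.653), with an opposite -0.41 on its other probe set, and Bdnf at 0.78 (0.701). The list's adjusted p was 0.242 without P14 litter 2, 0.399 without P14 litter 3, 0.571 without P28 litter 3, 0.0676 without P60 litter 2 and 0.0607 without P60 litter 3. It was 6.11e-05 without P14 litter 1, with a median of 0.44, and 0.335 in that fit with an estimated correlation. Bdnf, which encodes a neurotrophin, was the 1 member that passed in the restricted set, at 1.37 (adjusted p = 0.0249, and from 0.00289 to 0.993 over all settings).

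Actin cytoskeleton genes shifted down, with 15 of 40 higher and a median of -0.11 (adjusted p = 0.0351, and adjusted p = 0.221 with an estimated correlation). None passed over all probe sets, and 1 rose and 1 fell over the list alone. Members went both ways, with the troponin gene Tnnc1 at 1.61 (adjusted p = 0.289), Actb at -1.05 (0.368), the spine protein gene Dbn1 at -0.79 (0.644) and Rhoa at -0.69 (0.619). The list did not pass without P14 litter 1 (median -0.06, adjusted p = 0.229), P14 litter 2 (0.0506), P14 litter 3 (0.0861), P28 litter 3 (0.149) or P60 litter 2 (0.0739), and reached 0.286 over all settings. Blood cell genes (3 measured, median 1.19, adjusted p = 0.01) and choroid plexus genes (2 measured, median 1.07, adjusted p = 0.0351) were higher at P28, each with an adjusted p of 0.221 with an estimated correlation. Over the list alone 2 blood genes and 1 choroid plexus gene rose. Hba-a1 stood at 1.30 (adjusted p = 0.598), Alas2 at 1.19 (0.641), Slc4a1 at 0.80 (0.501), Folr1 at 1.41 (0.311), from a P14 mean below the Bacillus controls, and Clic6 at 0.74 (0.814). Without P14 litter 1, blood cell genes had a median of 0.68 and an adjusted p of 0.0737, and choroid plexus genes 0.80 and 0.144. Choroid plexus genes also did not pass without P14 litter 2 (0.0505), P28 litter 2 (0.0746) or P60 litter 3 (0.0569), and reached 0.261 over all settings.

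The remaining 24 lists had adjusted p from 0.0934, for endothelial and mural genes, to 0.996, for synaptic vesicle genes. With P14 litter 1 left out, glutamate receptor subunits were lower at P28 (median -0.23, adjusted p = 0.0245), heat shock genes higher (0.22, 0.0245) and extracellular matrix genes lower (-0.37, 0.0465) with the preset correlation. None of the 3 passed there with an estimated one (adjusted p = 0.207, 0.348 and 0.237). The first 2 also passed in the restricted set (0.0237 and 0.0144), and over all settings the 3 lists reached adjusted p of 0.568, 0.98 and 0.489. In the main fit GABAergic interneuron genes had a median of -0.06 (0.10 when that litter is left out), a mean of 0.01 and a test pointing down.

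In the restricted set the named genes for P28 against P14 were of several kinds. Beside Cadm1 at -2.13 (adjusted p = 0.00186), the falls included the matrix protein gene Npnt at -2.05 (0.0164), Cxadr at -1.81 (0.00849), the neuropeptide gene Grp at -1.54 (0.0436), the growth factor gene Igf2 at -1.43 (0.00582) and Kif21b at -1.44 (0.0202), whose other probe set stood at 0.16. Further falls were those of Flnc, Gtf2f2, Fgf13, Megf11 and Pdzd2. The rises included Igfbp6, which encodes a binding protein for insulin-like growth factors, at 3.88 (adjusted p = 0.00113), Marf1 at 2.28 (0.00113), whose other 2 probe sets stood at 0.18 and 0.32, and the opioid precursor gene Penk at 1.62 (0.0146). Lin28a, Lpar1, Itga10, Tmem63a and Zfp612 also rose from P14 means below the level of the Bacillus controls, as did Dusp28 and Jade2 from above it, and the P28 mean of Flnc lay below it. Over all settings the lowest adjusted p of the genes given with values here ran from 1.55e-06 for Cadm1 to 0.00934 for Grp, and the highest from 0.229 for Cadm1 to 0.993 for Penk.

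**Figure D2:**
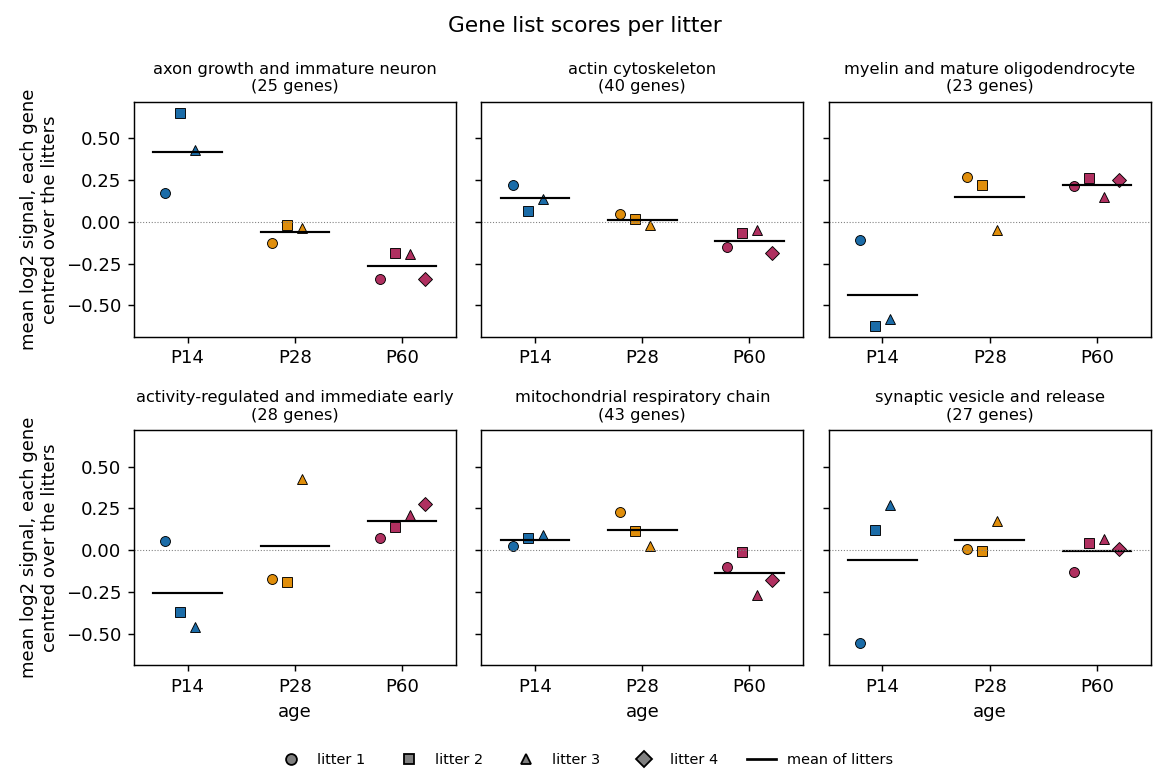
List scores in log2 units at P14, P28 and P60 for axon growth, actin, myelin, activity-regulated, mitochondrial and synaptic vesicle genes. Each point is 1 litter and each short line marks the mean of the litters of an age. Axon growth scores run from 0.169 to 0.652 at P14 and from -0.342 to -0.189 at P60, and P14 litter 1 has the lowest P14 score in that panel and -0.557 for synaptic vesicle genes.

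The comparison of P60 with P28 asks what changes after the critical period. Little stood out for single genes. Genes of the mitochondrial respiratory chain shifted down as a group in camera with its preset correlation, and not with an estimated one (adjusted p = 0.543). The largest changes were those of Ndufc1, Sdhd, Atp5e and Ndufb9, and no single member passed. Myelin genes, which with all litters had shifted up before P28 only with the preset correlation, did not pass as a group here.

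With all litters, limma called 0 of 20724 probe sets, with 1125 at an unadjusted p under 0.05 against 1036 expected by chance, and the smallest adjusted p was 0.894. In the restricted set limma also called 0, with 1490 at an unadjusted p under 0.05 and a smallest adjusted p of 0.0567. Without P14 litter 1, which enters only the shared estimate of the spread, 1 probe set passed, for Dctpp1, which fell (adjusted p = 0.0459) to a P60 mean below the Bacillus controls. Dctpp1 lies outside the naming rule and was chosen after its values were seen, and its other probe set stood at -0.15.

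Of 43 measured genes of the mitochondrial respiratory chain, 7 were higher at P60, with a median log2 change of -0.29 (camera, adjusted p = 2.14e-05, and adjusted p = 0.543 with an estimated correlation). None passed over all probe sets or over the list alone. The largest changes were those of Ndufc1 at -0.87 (adjusted p = 0.894), Sdhd at -0.80 (0.894), Atp5e at -0.65 (0.927) and Ndufb9 at -0.53 (0.894). The list's adjusted p was 6.65e-07 without P14 litter 1, where 5 members fell over the list alone, and 0.468 in that fit with an estimated correlation. In the restricted set the list had 1.3e-06 with the preset correlation. The other 29 lists had adjusted p from 0.196 to 0.992, and the median of the myelin list was 0.16 (adjusted p = 0.292). Median, mean and test differed in sign for GABA-A receptor subunits (0.20, -0.0017 and up), synaptic vesicle genes (-0.01, -0.06 and up), postsynaptic genes (-0.05, 0.05 and up) and ribosomal proteins (-0.01, 0.03 and down).

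The comparison of P60 with P14 spans the change from the cortex at eye opening to the young adult one. Of the genes for axon growth and neuronal immaturity, Gap43, Marcks, Ncam1 and Nrep fell, and of the myelin genes Mag and Ndrg1 rose. As lists, both shifted in camera with its preset correlation and not with an estimated one (adjusted p = 0.0531 and 0.154). The growth factor gene Igf2, which is also on the meningeal and fibroblast list, and the neuropeptide gene Grp fell. The meningeal and fibroblast list did not pass as a group (camera, adjusted p = 0.162). Rises included Scn4b, a sodium channel subunit gene, Hapln4, which encodes a link protein of perineuronal nets, and Il33, a cytokine gene. Capzb of the actin list and Sdhd and Uqcrb of the respiratory chain list fell. Both lists shifted down with the preset correlation and did not pass with an estimated one (adjusted p = 0.154 and 0.310). Of the 10 fits that each left out 1 litter, 5 called Gap43 and only 2 called Marcks, Ncam1, Mag, Hapln4, Capzb, Sdhd and Uqcrb. Without P14 litter 2 limma called 0 probe sets, and other splits of the litters did not exclude chance for this comparison.

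With all litters, limma called 82 of 20724 probe sets, 22 higher and 60 lower at P60, with 37 on chip A, 31 on chip B and 14 on chip C, and 3261 had an unadjusted p under 0.05. The count depended on single litters. It was 497 without P14 litter 1, 0 without P14 litter 2, 28 without P14 litter 3, 37, 40 and 37 without P28 litters 1, 2 and 3, and 18, 28, 260 and 8 without P60 litters 1, 2, 3 and 4. Where it was 0, the smallest adjusted p of the named genes was 0.0556. In the restricted set 441 passed, 170 higher and 271 lower. All 82 were among the 497 (153 higher, 344 lower), 75 were among the 441, and all 82 kept their sign in both. Both fits reuse arrays on which the 82 were called, so this agreement was largely fixed in advance. P14 litter 1 did not bear most of the larger counts out. Its median position was 0.695 over the 497 and 0.718 over the 441, where the P28 litters had 0.683 and 0.731, and it was nearer to P14 in 198 and in 171 of them.

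Over the 1 probe set kept per gene, the largest falls were those of Npnt, from 2100 ± 237 (SD, n = 3) at P14 to 416 ± 186 (SD, n = 4) at P60, a log2 change of -2.31 with a standard error of 0.279 and an adjusted p of 0.00937, and of Grp, from 4854 ± 760 to 1217 ± 488, at -2.03 (0.0178). Nrep, a gene of growing neurons, went from 7021 ± 1450 to 1945 ± 630, at -1.86 (0.011). Igf2 went from 6160 ± 237 to 1786 ± 352, at -1.79 with a standard error of 0.2 (0.00937), on a probe set of the g type. Further falls were those of Cacng4, an AMPA receptor auxiliary subunit gene, at -1.83 (0.0143), Ccn3 at -1.80 (0.0179), Cxadr at -1.71 (0.00937), whose other probe set stood at 0.11, and Enpp5 at -1.68 (0.011). Atp6ap1l, Uchl3, Nras and Ccnh fell by 1.60 to 1.72 on the log2 scale. P14 litter 1 stood with the other P14 litters for Igf2 (5914, against 6182 and 6386), Npnt (1829, against 2272 and 2198) and Gap43 (3187, against 3498 and 3013). These genes were called in the fit that included that litter, so this was partly fixed by their choice.

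The largest rise, again over the probe sets kept, was that of Igfbp6, from 324 ± 352 (SD, n = 3) to 2416 ± 552 (SD, n = 4), a log2 change of 3.23 with a standard error of 0.502 and an adjusted p of 0.0222. Its P14 signal was 723 in litter 1 and 60.9 and 186 in the others, and the change was 4.14 (0.000729) in the restricted set. Il33 rose from 552 ± 109 to 1778 ± 197, at 1.60 (0.00937), on a probe set of the i type. Scn4b rose from 347 ± 58.1 to 1172 ± 289, at 1.59 (0.011). Mag rose from 260 ± 114 to 775 ± 137, at 1.52 (0.0461), and Ndrg1 from 441 ± 26.4 to 1135 ± 120, at 1.29 (0.0116). Hapln4 rose from 1363 ± 187 to 3327 ± 925, at 1.22 (0.0491), with 0.30 on its other probe set. Cdk9 at 1.24 (0.0288), Drap1 at 1.27 (0.0308) and Adssl1 at 1.46 (0.0308) rose as well. Lin28a (0.0178), Zxda (0.0418) and Tmem63a (0.0116) rose from P14 means below the level of the Bacillus controls, so no size is given, and Zxda had an adjusted p of 0.0641 in the restricted set. Of the 10 fits that each left out 1 litter, 9 called Npnt, Igf2, Cxadr, Il33 and Scn4b, and 8 called Grp, Nrep, Enpp5 and Tmem63a. Over all settings the highest adjusted p of the 24 genes of this and the last paragraph ran from 0.108, for Npnt among others, to 0.243, for Zxda. Only 2 of the 10 fits called Mag, Hapln4, Adssl1, Drap1, Zxda, Marcks, Ncam1, Capzb, Sdhd and Uqcrb.

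**Figure D3:**
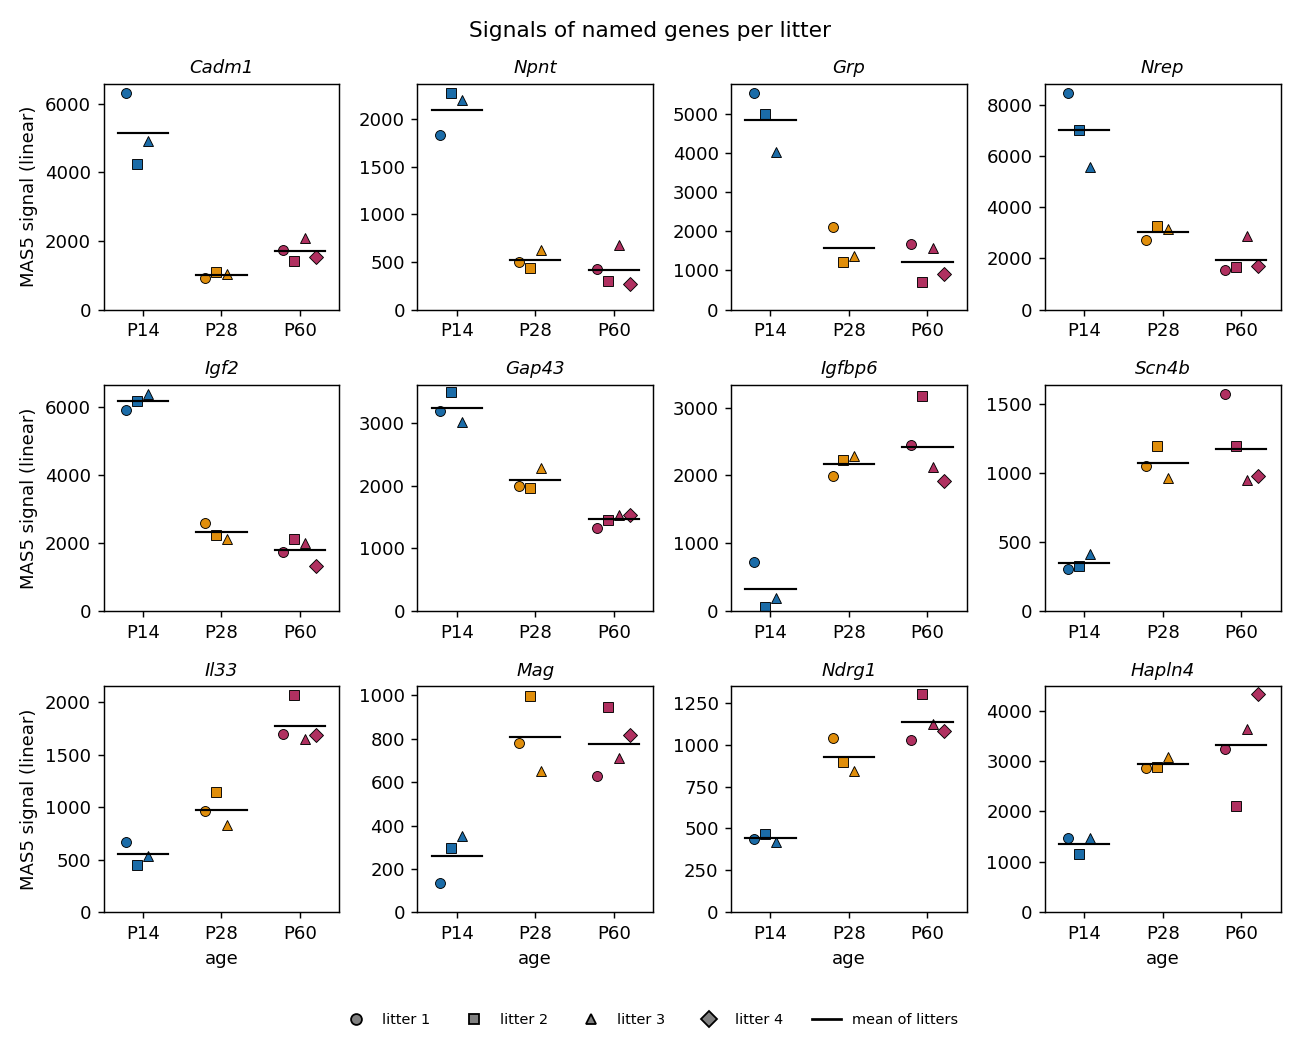
Linear MAS5 signal of 12 genes at P14, P28 and P60, with axes that start at 0. Each point is 1 litter and each short line marks the mean of the litters of an age. Igf2 stands between 5914 and 6386 at P14 and has a mean of 1786 at P60, and Scn4b goes from a mean of 347 to one of 1172.

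Of the axon growth and immature neuron list, 4 of 25 measured genes fell, 21 did not pass and none rose, with a median log2 change of -0.62 (camera, adjusted p = 1.67e-08, and adjusted p = 0.0531 with an estimated correlation). Beside Nrep these were Gap43, a growth cone protein gene, at -1.13 (adjusted p = 0.0179), Marcks at -1.31 (0.0297), with 0.28 on its other probe set, and Ncam1 at -1.02 (0.0311), with 0.76 on its other probe set. Adjusted over the list alone, 12 fell and 1 rose, Cntn2, at 0.68. The larger values that did not pass were Dpysl5 at -2.02 (0.0723), Fabp7, a radial glia gene, at -1.56 (0.0514) and Marcksl1 at -1.40 (0.147). Without P14 litter 1, 11 members fell, and in the restricted set 9 did, Marcksl1 among them at -2.04 (0.000729, and from 0.00011 to 0.451 over all settings). P14 litter 1 stood at 1932 for Marcksl1, against 7746 and 8171 in the other P14 litters.

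Of the myelin list, 2 of 23 measured genes rose, Mag and Ndrg1, 21 did not pass and none fell, with 21 higher and a median of 0.68 (camera, adjusted p = 1.67e-08, and adjusted p = 0.154 with an estimated correlation). Adjusted over the list alone, 13 rose and 1 fell, Gatm, at -0.55. Mbp stood at 1.28 (0.0613) and Mobp at 1.37 (0.235). Mag had a second probe set at 0.38, and 1 of the other 6 probe sets of Mobp stood at -0.43. Without P14 litter 1, 11 members rose, and in the restricted set 8 did, with Mobp at 2.26 (0.00928, and from 0.00109 to 0.553 over all settings). Gatm and Cntn2 were named because they opposed their lists.

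Activity-regulated genes shifted up, with 23 of 28 higher and a median of 0.35 (camera, adjusted p = 0.00489, and adjusted p = 0.400 with an estimated correlation). None passed over all probe sets and 3 rose over the list alone. Junb stood at 1.68 (0.0554), Fosb at 1.15 (0.103), Nr4a1 at 1.15 (0.186), with -0.47 on its other probe set, and Per1 at 1.14 (0.225). The list's adjusted p was 0.0982 without P14 litter 3, and without P14 litter 1 its median was 0.55 and 3 members rose. Actin genes shifted down, with 13 of 40 higher and a median of -0.08 (adjusted p = 0.00711, and adjusted p = 0.154 with an estimated correlation). Capzb, which caps actin filaments, fell at -1.43 (0.0381), while Cfl2 at -1.15 (0.0562), Dbn1 at -1.19 (0.146) and Cdc42 at -0.95 (0.0841) did not pass. The actin list had a median of -0.14 without P14 litter 1 and an adjusted p of 0.0936 in the restricted set. Respiratory chain genes shifted down, with 12 of 43 higher and a median of -0.23 (adjusted p = 0.00748, and adjusted p = 0.310 with an estimated correlation). Sdhd fell at -1.19 (0.0418), with 0.24 on its other probe set, and Uqcrb at -1.40 (0.0318), and the list's adjusted p was 0.113 without P60 litter 3.

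The other 25 lists did not pass between P14 and P60 with all litters. Of the cell type lists, medians and adjusted p were -0.48 and 0.146 for oligodendrocyte progenitors, 0.04 and 0.964 for astrocytes, 0.16 and 0.637 for microglia, -0.41 and 0.0615 for endothelial and mural cells, -0.03 and 0.162 for meningeal cells and fibroblasts, 0.80 and 0.190 for choroid plexus, 1.04 and 0.067 for blood cells, 0.59 and 0.409 for the hippocampal formation, and -0.17 and 0.346 for GABAergic interneurons. Of the synaptic and channel lists they were -0.28 and 0.570 for GABA-A receptor subunits, -0.09 and 0.828 for glutamate receptor subunits, 0.05 and 0.971 for synaptic vesicles, -0.05 and 0.928 for the postsynaptic density, 0.18 and 0.146 for voltage-gated channels, and 0.16 and 0.971 for neurotrophins. They were -0.01 and 0.606 for neurofilaments, -0.21 and 0.146 for extracellular matrix, 0.06 and 0.825 for proliferation, 0.34 and 0.864 for glycolysis, 0.03 and 0.582 for cholesterol synthesis, 0.11 and 0.756 for ribosomal proteins, 0.32 and 0.190 for MHC class I and complement, 0.14 and 0.338 for insulin-like growth factor, 0.26 and 0.146 for the circadian clock, and 0.19 and 0.338 for heat shock. The median and the test, or the median and the mean, differed in sign for astrocytes (mean 1.46e-05, test down), glutamate receptors (mean 0.02), synaptic vesicles (test down), cholesterol synthesis (mean -0.05) and neurotrophins (mean -0.02). Leaving out P14 litter 1 turned the medians of glycolysis to -0.14, cholesterol synthesis to -0.08, synaptic vesicles to -0.23, astrocytes to -0.04 and neurofilaments to 0.06. It brought those of the hippocampal formation to 0.30, endothelial and mural cells to -0.16, blood cells to 0.63, microglia to 0.03, choroid plexus to 0.53 and meningeal cells to -0.18. It also brought those of extracellular matrix to -0.46, the postsynaptic density to -0.16, GABA-A receptors to -0.16, proliferation to 0.20, insulin-like growth factor to 0.20 and neurotrophins to 0.05, and moved the rest by less than 1.5 times. Oligodendrocyte progenitor genes passed downward without P14 litter 1 (0.0247, and 0.245 with an estimated correlation) and in the restricted set (0.0104). Extracellular matrix genes passed only without P14 litter 1 (0.0427, and 0.245 with an estimated correlation) and heat shock genes only in the restricted set (0.0104). Over all settings these 3 lists reached adjusted p of 0.31, 0.337 and 0.978. Xist, the 1 sex-linked gene measured, had log2 changes of -0.44 from P14 to P28, 0.62 from P28 to P60 and 0.18 from P14 to P60. The first and last were 0.26 and 0.87 without P14 litter 1. In P14 litter 1 Xist had a score of 1.44, against -0.40 and -0.87 in the other P14 litters, so its change with age is not settled. The sex of the animals is not given in the sources used here, so sex and age could not be told apart for this gene.

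Further genes passed in the restricted set between P14 and P60. Falls included Dpysl5 at -2.23 (adjusted p = 0.0048), the receptor gene Met (0.0244), Efna2, an ephrin gene (0.00894), and Camk2a (0.0102), which stood at -0.60 (0.753) with all litters and at 0.24 without P14 litter 3. Gpr6, Tmem177, Tbc1d22b and Gtf2f2 fell as well, and so did Pip5k1c and Adcyap1r1, which have other probe sets of the opposite sign. In that set the P60 means of all these falls but Dpysl5 and Pip5k1c lay below the Bacillus controls, so no size is given. Rises included Marf1 at 2.44 (0.000729), Jade2 at 2.11 (0.00405), Lpar1 (0.0103) and Rasd1 (0.0475). Xaf1, Myh7 and Ccdc169 rose as well, and in that set the P14 means of Lpar1, Rasd1, Xaf1, Myh7 and Ccdc169 lay below the Bacillus controls. Over all settings the lowest adjusted p of the 8 genes given with values here ran from 0.000158 for Dpysl5 to 0.0244 for Met, and the highest from 0.23 for Jade2 to 0.911 for Camk2a.

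The 3 ages together were tested with limma's moderated F-statistic. With all litters 23 probe sets passed, with 2337 at an unadjusted p under 0.05 and a smallest adjusted p of 0.0145. The count was 130 without P14 litter 1, 1 without P14 litter 2, 0 without P14 litter 3, and 0 without each of the P28 litters. It was 2, 6, 32 and 0 without P60 litters 1, 2, 3 and 4, and 221 in the restricted set. A peak or trough at P28, in which both neighbouring comparisons pass in limma with opposite signs, was found for 0 probe sets with all litters, without P14 litter 1 and in the restricted set, and for a median of 0 in 20 simulated draws without change. At an unadjusted p under 0.05 the 2 comparisons it needs had 1632 and 1125 probe sets. Past the adjusted threshold, P60 against P28 had 0 with all litters, 1 without P14 litter 1 and 0 in the restricted set. The number of peaks or troughs was thus fixed at or near 0 in advance, and it does not exclude such patterns.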

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

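Of the tests in this part, those on degraded RNA, on white matter and on the RNA of the P60 litters were chosen only after the result was seen, and so were the restricted set, the measured margin in the test of exchanged array labels, and the comparisons of single genes in P14 litter 1. The other tests were chosen earlier.

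Among the named genes, 4 had 1 P60 litter far from the other 3. Nrep, a gene of growing neurons, stood at 2885 in P60 litter 3, where the next litter had 1703, and Nras at 847 in the same litter, where the next had 510. Il33 stood at 2072 in P60 litter 2, above 1696, and Adssl1 at 453 in P60 litter 1, above 331. Nrep and Nras were thus nearest to their P14 levels in that litter, and Il33 and Adssl1 farthest from theirs. A gap this large relative to the range was looked for in 44 groups of 4 litters, 25 of them named genes, and chance gives it in about 5% of groups. No explanation for these 4 was tested.

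The control transcripts, which no comparison used, set P14 litter 1 apart. Its ratio of 3' to 5' signal was at least 9.57 for Gapdh and at least 12.2 for Actb, where the highest values elsewhere were 1.32 and 1.5. Its Gapdh ratio was at least 8.99 times the highest of the other 9 arrays of a chip type, which is what degraded RNA or shortened cRNA would give. Which genes this affected was not measured.

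No sign of carried-over hippocampus, meninges, vessels or blood was found in P14 litter 1. Of these 4 lists, the highest stood at percentile 63.8 among 10000 random lists of its size. The lists held 5, 9, 15 and 3 measured genes in that order. How degraded RNA would move them was not measured, so carry-over is not excluded. White matter from beneath V1 stays open, since the myelin list stood at percentile 99.1. Of its 23 genes 15 were higher than in the other P14 litters and 8 lower, and an older animal would raise myelin genes too. A sample of another age remains open. On an axis from P14 to P60 built without it, P14 litter 1 lay at 0.672, which is 0.136 above the lowest P28 litter, but on chip C it lay at 0.552, below the lowest P28 litter's 0.635. Single genes stood with P14, such as Igf2 at 5914 (P14 litters 2 and 3 at 6182 and 6386) and Mbp at 2681 (2519 and 2973), but others such as Marcksl1 at 1932 (7746 and 8171) did not. Igf2 and Mbp were named from fits that included P14 litter 1. Such naming favours genes in which it stood with P14, so they decide nothing on its age. Over the 497 probe sets called between P14 and P60 without it, it was nearer to P14 in 198. The chips thus point both ways, and where degraded RNA of a P14 litter would fall on that axis was not measured.

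P60 litters 1 and 4 stood apart on chips A and B and P60 litter 2 on chip C. A property of their RNA would show on every chip. On chip C the lower of litters 1 and 4 correlated with the other arrays by 0.0481 more than litter 2 did. That litter 2 was lowest there was part of the pattern, so this difference is no separate test. Litters 1 and 4 stood at 0.920 and 0.908 on chip C, where arrays other than P14 litter 1 and P60 litter 2 ran from 0.898 to 0.921. If the chip C labels are right, this argues against a property of the RNA of litters 1 and 4 as the whole cause. A narrower range of signals alone remains open. In rank correlations litters 1 and 4 still lay below litters 2 and 3, by 0.0234 on chip A and 0.0517 on chip B. Chip A lay between the bounds set for and against it. Chip B lay past the bound against it, which had to be passed on both chips. Exchanged array labels between chip types could not be decided. For genes on more than 1 chip type, all 4 litters correlated best with themselves across chips, but only 1 of the 4 by more than 2 standard errors. No biological explanation was tested for either pattern, as the labels give none.

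Other splits of the same litters were fitted for each comparison. For P28 against P14 the 10 splits are too few to exclude chance. The real split gave 1 probe set and 6 lists, and the highest other splits gave 0 and 4. For P60 against P28 the real split gave 0 probe sets, which every one of the 35 splits must match, so they decide nothing there, with 1 in the highest other. Chance was not excluded for its 1 list, since 22 of 35 splits gave as many, and the highest other gave 7. For P60 against P14 chance was not excluded either, since 2 of 35 splits gave as many probe sets as the real 82, the real one included, and 5 of 35 as many as its 5 lists, with 6 the highest other. The split with more set P14 litter 1 and P60 litters 1 and 4 against the rest and gave 267. It follows the arrays that stood apart and points to a structure of the samples that is not age. Without those arrays the real comparison gave 441, but no splits were run for that set, so the 441 does not exclude such a structure. For the 3 ages together the real grouping gave 23 probe sets and the highest other gave 1. Of 100 groupings 1 was as large, the real one itself, which argues against a random grouping of the litters. The 100 were not all the possible groupings, and whether any followed the arrays that stood apart was not recorded. A structure of the samples that is not age is therefore not excluded here. For a peak or trough at P28 the real 0 must be matched by all 100 groupings, so they decide nothing, with 1 in the highest other.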

How the results depend on the processing

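The restricted set and the set without the P60 arrays that stand apart were tests chosen only after the result was seen, and the cause was not tested where none is given. Over all alternatives, the 31 gene results that passed gave 445 values on the same side of the threshold and 265 weaker ones, and none reversed. The 75 gene results that did not pass gave 1550 alike, 146 that passed and 7 reversed, and the 12 lists that passed gave 249 alike and 51 weaker. Probe sets called for P28 against P14, P60 against P28, P60 against P14 and the 3 ages were 1, 0, 82 and 23 in the main analysis. They were 208, 0, 441 and 221 in the restricted set, but 0 in each without the P60 arrays that stand apart only. Array weights gave 1163, 0, 3621 and 3024. Other splits of the litters with array weights gave up to 50 for P28 against P14, 2612 for P60 against P28 and 5167 for P60 against P14, so the 3621 is not reliable, and no splits were run for the 3024. The filter at the 70th percentile gave 2, 0, 135 and 37, partly because fewer probe sets were tested. Without a variance trend the last 2 counts were 51 and 6, with quantile normalisation 87 and 15, and with median scaling 109 and 8. With only the 2 ages compared in the fit, with fewer litters for the spread, limma called 0 for P28 against P14 and 0 for P60 against P14. The constant at the 40th percentile gave 2 for P28 against P14. Median scaling moved the median of all probe sets between P28 and P60 from -0.00834 to -0.155, so P60 calls are relative to such shifts. It also made 11.9% of the P60 against P14 calls rises (13 of 109), where the main share was 26.8%. Leaving out 1 litter gave 0 to 26 for P28 against P14, 0 to 1 for P60 against P28, 0 (without P14 litter 2) to 497 (without P14 litter 1) for P60 against P14 and 0 to 130 for the 3 ages, and a peak at P28 stayed at 0. Lists called in the 3 comparisons were 6, 1 and 5, and 0, 0 and 0 with estimated correlations, which allow for genes that vary together. Leaving out 1 litter gave 3 to 6, 1 to 2 and 4 to 7. Quantile normalisation gave 3 for P60 against P14, median scaling 2 and the 70th percentile filter 3 for P60 against P28, and only the 2 ages compared 3 and no apart-standing P60 arrays 3 for P28 against P14. The litter number as a block gave 0, 0, 0 and 0 probe sets. Whether the numbers pair the litters is not settled. Correlations of deviations between litters of the same number ran from -0.0626 to 0.132, with 1 of 9 pairs above 0.1. The own number correlated best in 9 of 18 looks at another age, which are not independent. The labels do not say that a number is shared between ages, and the block takes up degrees of freedom. Reversed values, none past the threshold, were those of Clic6 between P14 and P28, at -0.037 without P14 litter 1 and in the restricted set (up to 1.17 without P14 litter 3), Camk2a between P14 and P60, at 0.24 without P14 litter 3 (-1.75 without P14 litter 1), and Gtf2f2, at 0.08 without P14 litter 2, 0.10 without P14 litter 3, 0.22 without P60 litter 2 and 0.24 without P60 litter 3 (-0.69 without P14 litter 1). The constant at the 5th percentile, a floor, no filter, a fold change of at least 1.5 and the mean of a gene's probe sets kept every count they apply to within 1.5 times. Signal over background limits genes near the Bacillus control levels of 98.4, 153 and 252, whose changes depend on the constant.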

Other observations

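Of the tests in this part, the comparison with P14 litter 1 as a control was chosen only after the result was seen, and so were the genes and list scores singled out here. The share of the change present at P28 was tested as planned.

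Beyond the named genes, some single probe sets that passed between P14 and P60 were picked by hand after their values were seen. They come from no fixed list, and whether genes of their kinds were more frequent among the falls than elsewhere was not tested. Shtn1, which encodes shootin, a protein of axon formation, stood at -1.13 (limma, adjusted p = 0.0308). The neuron navigator genes Nav1 at -1.07 (0.0308) and Nav3 at -1.43 (0.0311) fell as well, as did the teneurin gene Tenm3 at -1.12 (0.0308). Plppr1 at -1.02 (0.0406) and Plppr4 at -1.39 (0.0345), which encode membrane proteins of neurite and synapse formation, were among them, and so was the Notch ligand gene Dner at -1.19 (0.0222). Second probe sets of list members passed too, with Stmn2 at -1.48 (0.011) and L1cam at -1.55 (0.0111). In the restricted set these 9 probe sets had adjusted p of 0.043, 0.0292, 0.0281, 0.0267, 0.0307, 0.0292, 0.0236, 0.00796 and 0.0103 in that order. The probe sets of this and the next paragraph that passed are among the 82 called with all litters, which all passed without P14 litter 1 too, and their values under the other settings were not looked at one by one. Other probe sets of Nav1, Nav3 and Dner went the other way, at 0.48, 0.50 and 0.23.

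Further single genes were picked in the same way. Dnmt3a, which encodes a DNA methyltransferase, stood at -1.49 (limma, adjusted p = 0.00937, and 0.00451 in the restricted set). A probe set of Mef2c, a transcription factor gene that responds to activity, stood at -1.40 (0.011, and 0.00451), while its brightest probe set on chip A stood at -0.12. Col1a1, a collagen gene of the meninges and vessels, had a probe set that fell (0.0253, and 0.0103) to a P60 mean below the Bacillus controls. Junb, an immediate early gene, rose on its i-type probe set, at 2.38 (0.0117, and 0.0151 in the restricted set), but did not pass on the probe set kept for the gene, at 1.68 (0.0554).

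The litters' list scores were compared between ages. Between P14 and P60, 11 of 30 lists had no overlap of the litters' scores, 5 with all P60 litters above and 6 with all below, where chance gives 5.71%. Between P14 and P28 it was 8 of 30, where chance gives 10%, and between P28 and P60 7 of 30, where chance gives 5.71%. Lists share litters and are not independent, so these counts were not tested against chance. Voltage-gated channel genes, as a group, had scores from 0.0209 to 0.24 at P60 and from -0.222 to -0.0332 at P14. Endothelial and mural genes had scores from 0.0678 to 0.313 at P14 and from -0.154 to -0.0398 at P60. Neither list passed camera. Axon growth and actin scores fell in order over all 3 ages without overlap. Actin scores ran from 0.0632 to 0.222 at P14, from -0.0206 to 0.0459 at P28 and from -0.188 to -0.0503 at P60. Between P28 and P60, however, the axon growth and actin lists did not pass camera (adjusted p = 0.196 and 0.292).

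A hypothesis was that most of the change between P14 and P60 is present by P28, so that the critical period begins with the larger part of it done. Differences that share P14 or P60 arrays would give that impression by chance. Probe sets were therefore chosen on some litters and measured on others, and the share of the change present at P28 was 0.759 to 1.38 over chips and exchanges, above the bound of 0.5 set against shared arrays. The same measure gave P14 litter 1, a sample labelled with the starting age, a share of 0.974 to 1.33. For probe sets chosen as falls its share was 1.10 to 1.81, above the bound each time. For those chosen as rises its share was 0.244, 0.414 and 0.248 on chips A, B and C in 1 exchange, below the bound, and 1.37, 0.863 and 0.703 in the other, while the P28 litters had 0.755 to 1.19. A bound that a P14 litter passes in most of these cases does not separate an early change from noise, so it was set wrongly, and P14 litter 1 is itself of poor quality. The hypothesis remains open. Only in the rises of 1 exchange did P14 litter 1 lie below the bound on each chip with the P28 litters above it. In the rises of the other exchange both lay above it, so these values do not decide the question.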
